A study of Homo sapiens with 4 samples.

How the data were processed

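Total RNA of MDA-LM2 cells was sequenced from 4 libraries, 2 per group, per the labels. Reads were aligned with STAR 2.7 to hg38, per the submitters' processing notes. Inclusion levels of skipped exons were estimated by the authors with MISO, per the file headers, and deposited as a fraction between 0 and 1 with an interval and with read numbers per class of compatibility. The version of MISO, its event annotation, the level of the interval and whether the 2 libraries of a group were merged are not given in the sources used here. The authors' deposited comparison of the groups gives the ψ difference, siSNRPB2 minus siCtrl, and the Bayes factor, a ratio of the evidence for a difference over none that reaches at most 1e+12 (1929 events). Each listed event had at least 20 reads of any class. Because there is 1 value per group, the difference between groups could not be set against a spread between replicates, and the authors' values are given without SD or n.

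Reads compatible only with inclusion or only with exclusion were called informative. An exon was tested with at least 20 informative reads in each file, keeping the event with the most such reads for each skipped exon. It was called with a Bayes factor of at least 10 and a ψ difference of at least 0.1. The median tested exon had 158 informative reads in siCtrl and 137 in siSNRPB2, and median ψ intervals 0.06 and 0.07 wide. Events were assigned to genes of GENCODE release 29 by position: 99.9% had a gene, and the skipped exon of 95.6% was an annotated exon. Exon GC content came from annotated transcript sequences. Splice site scores, the polypyrimidine share and U12-type sites need a genome sequence and were not analysed here.

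Random lists and sets of exons (10000 each) were matched on 5 groups of reads and 5 of mean ψ, and random lists of genes for reads per gene (10000 each) on 10 groups of reads. Percentiles of 2.5 or less, or 97.5 or more, were read as standing apart. Reads per gene were those compatible with either isoform on the gene's deepest event, scaled to the file's total over 1 event per gene, on the log2 scale with a pseudocount of 1, for genes with at least 20 reads on average. Fisher's exact test used Benjamini-Hochberg adjustment over all tested exons. The noise factor was the median chi-square of inclusion-only against flanking reads over its expectation, in exons with ψ of at least 0.95 in both files and no exclusion-only reads. In such exons ψ rests on these same reads. Exons with a large shift between the files are therefore left out, and the factor can be too low. It was also taken within each of 5 quintiles of those exons by reads, with a 95% bootstrap interval over exons, and each exon's reads were divided by the factor of the quintile in which its own reads fall. Dividing reads by either factor was chosen after the data were seen. Exact intervals on undivided counts cover counting error only, and that of the share of lower calls treats exons as independent. Bootstrap intervals cover the sampling of exons or genes. No interval computed here covers differences between replicates.

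Gene lists (17), thresholds and the rule for named genes were set before the data were examined. The rule names SNRPB2, SNRPA1, PLEC, ERRFI1, MDM4, BCL2L1, MCL1, CASP2, CD44 and NUMB where measured. It adds the 10 called exons per direction with the largest ψ difference, at least 50 informative reads in each file and 1 per protein-coding gene, up to 4 called genes per list, the 8 highest and lowest genes by reads with at least 100 reads, and up to 3 genes per list by reads. The lists covered U2 and 3' splice site factors, core spliceosome, SR proteins and hnRNPs, nonsense-mediated decay, apoptosis, the p53 pathway, mitosis, DNA repair, genes with transition-associated exons, actin and adhesion, chromatin, trafficking, interferon genes, stress response, and epithelial, mesenchymal, and blood and endothelial markers. Every tested exon of a listed gene was counted. Alternatives changed the thresholds, the read minimum, the estimator, the matching and the scaling 1 at a time.

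The read test was tested on simulated data drawn for the 18682 tested exons, 200 of them changed. With independent reads it recovered 49% of exons lower by 0.3 and 9% of those higher by 0.15, with 0 unchanged exons called. With each read present 9 times and treated as independent, it called 2546 unchanged exons. Dividing by 9 removed these calls and recovered 0% of the changed exons. Among exons with at least 1000 informative reads over both files (56 changed), it recovered 71.4% of those lower by 0.3 and 7.14% of those higher by 0.15. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.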

Results

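Skipped-exon inclusion was measured by RNA sequencing in MDA-LM2 cells, a lung-metastatic derivative of the human breast cancer cell line MDA-MB-231, after transfection with small interfering RNAs. SNRPB2 encodes U2B'', a protein of the U2 small nuclear ribonucleoprotein, which recognises the branch point upstream of the 3' splice site. Per the labels, 2 libraries came from cells with SNRPB2 knocked down (siSNRPB2) and 2 from control transfections (siCtrl), all taken 48 h after transfection, with 2 independent siRNAs and a knockdown of over 95% by quantitative PCR. The files hold 1 inclusion level (ψ, the fraction of transcripts that keep the exon) per event and group, so no difference below has a replicate check. The siCtrl file listed 42159 events with 100579230 reads assigned to events, and the siSNRPB2 file 42670 events with 93580246; a read can be assigned to several overlapping events. In siCtrl 10124300 and in siSNRPB2 8793710 of these fitted only the isoform with the exon, and 1268806 and 1128806 only the isoform without it. No event in the files used here was assigned to SNRPB2, so its own level was not analysed here.

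The first question was which exons are included differently when SNRPB2 is depleted. Among 18682 skipped exons in 7402 genes with at least 20 informative reads in each file, 1422 were called lower and 1332 higher in siSNRPB2, in 2092 genes together. Among exons with at least 50 such reads in each file, the strongest decreases were in PICALM, a clathrin adaptor, where ψ was 0.16 in siSNRPB2 and 0.88 in siCtrl, and in KDM1A, a histone lysine demethylase, where it was 0.18 and 0.89. The strongest increase was in PTBP2, a splicing regulator of the polypyrimidine tract binding family, where ψ was 0.97 in siSNRPB2 and 0.15 in siCtrl. With reads divided by the noise factor of all exons, described below, none of the 3 passed Fisher's exact test (adjusted p = 1, 0.779 and 0.0884). With the factor of exons of similar depth PTBP2 passed the same test (2.02e-03), but not at the upper end of that factor's 95% bootstrap interval (0.0728). Directions were nearly balanced: 51.6% of calls were lower (exact 95% interval 49.7 to 53.5, counting error only), and the median ψ difference over all tested exons was 0. The median difference was -0.27 among lower calls and 0.27 among higher calls.

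**Figure D1:**
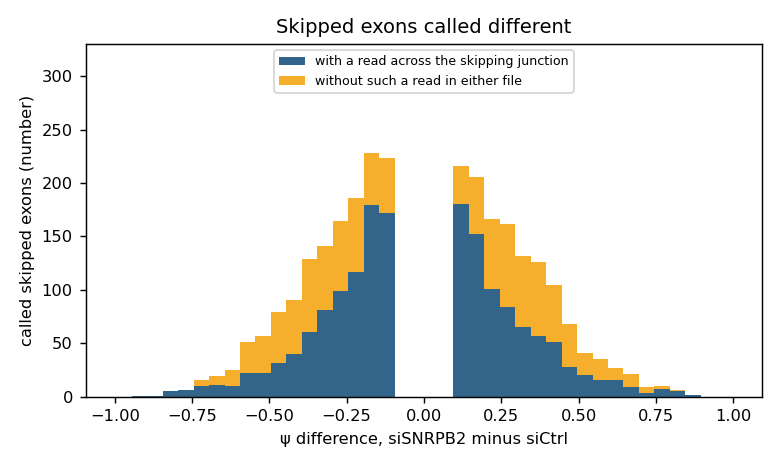
Number of called skipped exons (vertical axis) by ψ difference, siSNRPB2 minus siCtrl (horizontal axis, fraction), in stacked bars. Bars divide the 2754 calls into those with a read across the skipping junction and the 1088 without such a read in either file; both kinds lie on both sides of 0.

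The PICALM exon lies at chromosome 11, 85978070 to 85978093 (hg38), in coding sequence, and had 11 inclusion-only and 47 exclusion-only reads in siSNRPB2 against 53 and 4 in siCtrl. The KDM1A exon, at chromosome 1, 23044427 to 23044486, is also coding and had 49 exclusion-only reads in siSNRPB2 against 1 in siCtrl. The PTBP2 exon, at chromosome 1, 96806419 to 96806452, had 190 inclusion-only and 4 exclusion-only reads in siSNRPB2 against 11 and 58 in siCtrl. All 3 had the largest Bayes factor that occurs in the authors' deposited table, 1e+12. The other lower calls with the largest differences were in NT5C2 (ψ 0.25 in siSNRPB2 and 0.95 in siCtrl), PCBP4 (0.33 and 0.95), ADARB1 (0.28 and 0.89) and RHBDD2 (0.22 and 0.8), which had exclusion-only reads, and in NOP58 (0.37 and 0.96), TP53BP1 (0.36 and 0.95), UQCC1 (0.31 and 0.89) and BRAT1 (0.31 and 0.89), which had none in either file. The other higher calls were in OSBPL6 (0.97 and 0.19), SYNRG (0.87 and 0.14), ATP5F1B (0.9 and 0.21), PRUNE1 (0.93 and 0.26) and ABLIM3 (0.75 and 0.13), with exclusion-only reads, and in MARF1 (0.93 and 0.26), WWC1 (0.93 and 0.26), VIRMA (0.98 and 0.33) and MYO9B (0.98 and 0.35), with none. Over all events of the RHBDD2 exon the median ψ difference was -0.335, against -0.58 for the event used. Where no read crosses the skipping junction, ψ rests on how reads spread between the exon and its neighbours.

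**Figure D2:**
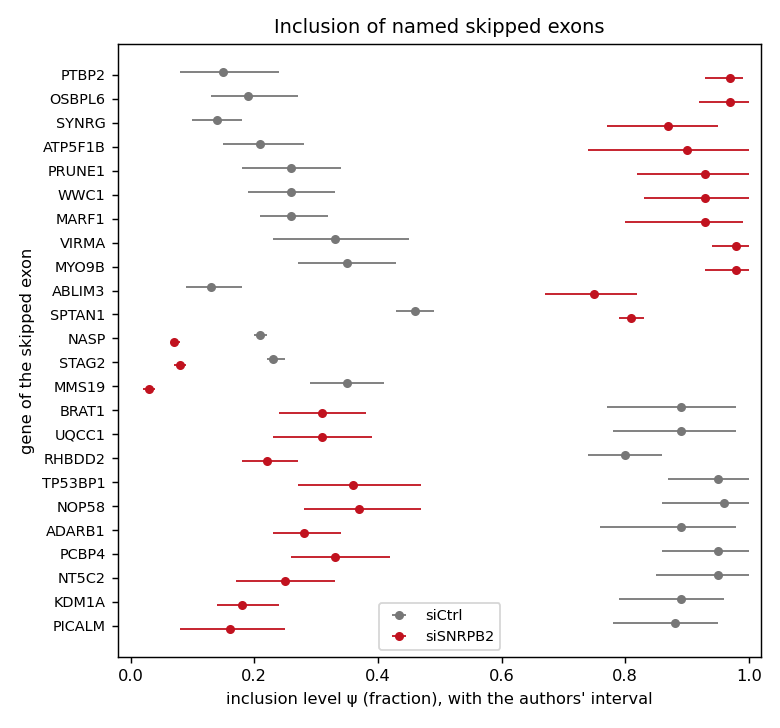
Inclusion level ψ (horizontal axis, fraction) of the named skipped exons (vertical axis, gene), with points for the authors' values and bars for their intervals in siCtrl and siSNRPB2. PICALM lay at 0.16 in siSNRPB2 against 0.88 in siCtrl, and PTBP2 at 0.97 against 0.15; NASP, STAG2, MMS19 and SPTAN1 were chosen after their values were seen.

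Of the genes named in advance, MDM4, NUMB and SNRPA1 had called exons, and PLEC, ERRFI1, BCL2L1, MCL1, CASP2 and CD44 had none. PLEC is a cytoskeletal linker and ERRFI1 an inhibitor of the epidermal growth factor receptor. The 3 tested PLEC exons had a ψ of 1, 0 and 0 in both files, where little difference can show. The ERRFI1 exons, with no exclusion-only read in either file, differed by -0.04 (0.57 and 0.61) and 0.07 (0.16 and 0.09); the second had a Bayes factor of 65.65 in the authors' deposited table and missed only the minimum difference of 0.1. An exon of MDM4, a negative regulator of p53, at chromosome 1, 204537430 to 204537497, was called lower at 0.11 in siSNRPB2 and 0.3 in siCtrl. NUMB, a Notch inhibitor, had 1 exon called lower (0.31 and 0.47, with no exclusion-only read in either file) and 1 called higher (0.88 and 0.72). The exons of BCL2L1, MCL1 and CASP2, all regulators of apoptosis, differed by 0, -0.01 and 0.02, with ψ near 0 or 1 in both files (0.03 and 0.03, 0.99 and 1, 0.03 and 0.01), and no CD44 exon was called. The small MCL1 difference had a Bayes factor of 1e+12 in the authors' deposited table, with 44 exclusion-only reads in siSNRPB2 and 3 in siCtrl (Fisher's exact test, adjusted p = 5.38e-11; 1 with reads divided by the noise factor of all exons). SNRPA1, which encodes the binding partner of U2B'', had an exon called lower at 0.52 and 0.84, with no exclusion-only read in either file. Another coding exon of SNRPA1 went the other way (ψ 1 in siSNRPB2 and 0.96 in siCtrl, Bayes factor 1e+12), but missed the minimum difference. It had 0 exclusion-only reads in siSNRPB2 and 24 in siCtrl.

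Called exons were found in most groups of genes, in both directions. Among U2 and 3' splice site factors, 5 of 54 exons were called lower and 4 higher, including DDX42 (0.66 and 0.99) and RBM39 (0.86 and 0.55, with no exclusion-only read in either file). Other core spliceosome genes had 4 lower and 4 higher of 101, led by USP39 (0.79 and 0.12), which also had none. SR proteins and hnRNPs had 15 lower and 9 higher of 185, with TIA1 higher (0.92 and 0.09) and RBM5 lower (0.43 and 0.92). In nonsense-mediated decay 1 was lower and 4 were higher of 40, with MAGOHB higher (0.5 and 0.17). Apoptosis genes had 7 lower and 4 higher of 93, with CFLAR lower (0.05 and 0.51), and the p53 pathway 6 and 3 of 61, with DDB2 lower (0.51 and 0.88). Mitosis and cytokinesis had 23 lower and 18 higher of 233, with CDC25C lower (0.09 and 0.88) and NUMA1 higher (0.84 and 0.08). DNA replication and repair had 16 and 20 of 279, with ORC4 higher (0.66 and 0.03). Genes with exons associated with the epithelial to mesenchymal transition had 22 and 17 of 224, counting any tested exon, with TCF7L2 lower (0.04 and 0.57) and ABI1 higher (0.87 and 0.41). Actin and adhesion genes had 8 and 12 of 236, with MACF1 lower (0.5 and 0.98) and ITGB1 higher (0.34 and 0.04). Chromatin regulators had 31 and 25 of 322, with MBD1 higher (0.67 and 0.03), and membrane trafficking 18 and 16 of 259, with MON2 lower (0.08 and 0.91) and VTI1A lower (0.2 and 0.94). Interferon-stimulated genes had 3 and 4 of 51, and stress response genes 0 and 3 of 51, all named members without exclusion-only reads. Mesenchymal markers had 1 and 5 of 26, epithelial markers 0 of 6 and blood and endothelial markers 0 of 2.

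The median ψ difference did not separate lists, since it was exactly 0 for 14 of the 16 lists with at least 5 exons. Against 10000 random lists matched on reads and mean ψ, as a description of these files, the other medians lay at the percentiles 15.9 (epithelial markers) and 91.2 (mesenchymal markers). The number of called exons, which is not tied in this way, lay between the percentiles 8.91 (core spliceosome) and 80.3 (genes with transition-associated exons) over these lists. Exons called lower had a median length of 119 nt, near the 121 nt of all tested exons but below the 125 to 133 nt in the middle 95% of sets matched on reads and mean ψ. Matching on reads alone ended that difference (percentile 41.9).

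Fisher's exact test (2-sided) on inclusion-only and exclusion-only reads compares those files, not the conditions. With Benjamini-Hochberg adjustment, 987 exons had a lower and 985 a higher share of inclusion-only reads by at least 0.1, and 674 of the lower and 639 of the higher calls had an adjusted p under 0.05 in the same direction. By this exact test PICALM (adjusted p = 1.41e-14), KDM1A (7.32e-25), PTBP2 (2.83e-38) and TCF7L2 (1.63e-28) were among them. By gene list, exons with an adjusted p under 0.05 and a read share different by at least 0.1 were counted, whether called or not. Counts adjusted over all exons and adjusted over the list alone were 35 and 36 for membrane trafficking, 35 and 35 for chromatin regulators, 29 and 32 for genes with transition-associated exons, 29 and 30 for mitosis, 17 and 17 for actin and adhesion, 16 and 15 for DNA repair, 15 and 16 for SR proteins and hnRNPs, 11 and 11 for the core spliceosome, 10 and 10 for apoptosis, 6 and 6 for nonsense-mediated decay, 5 and 6 for U2 factors, 5 and 5 for the p53 pathway, 4 and 4 for mesenchymal markers, 3 and 3 for interferon genes and 1 and 0 for the stress response. However, in 3901 exons included in nearly all transcripts, the median chi-square of inclusion-only against flanking reads between the files was 9.35 times its expectation for independent reads. The files are the 2 conditions, so this factor may hold differences between conditions as well as reads that are not independent. The selection of these exons by ψ leaves out large shifts, which can make the factor too low. With reads divided by this factor, 4 exons had an adjusted p under 0.05 and 258 an unadjusted one. The factor rose with depth, from 5.99 in the quintile of these exons with the fewest reads to 11.8 in the deepest, and the number of exons that passed depended on it. By the exact test on scaled reads they were in NASP, a histone chaperone (ψ 0.07 in siSNRPB2 and 0.21 in siCtrl; adjusted p = 4.89e-22), STAG2, a cohesin subunit (0.08 and 0.23; 2.18e-03), SPTAN1, a spectrin (0.81 and 0.46; 4.63e-03), and MMS19, an iron-sulfur assembly factor (0.03 and 0.35; 1.21e-02). By the exact test with the factor 11.8 for every exon, only NASP of the 4 passed (8.71e-17, against 0.0641 for STAG2, 0.0719 for SPTAN1 and 0.447 for MMS19). With the factor of each exon's own read quintile all 4 passed, and PTBP2 as well (exact test, adjusted p = 2.02e-03). At the upper end of the factor's 95% bootstrap interval only NASP of these exons passed (exact test, adjusted p = 0.223 for STAG2, 0.269 for SPTAN1, 0.125 for MMS19 and 0.0728 for PTBP2). On simulated reads the scaled test recovered 0% of exons lower by 0.3 at the depth of all exons and 71.4% of those with at least 1000 informative reads, but only 7.14% of exons of that depth higher by 0.15, so absence from these 4 says little about an exon of lower depth or with a smaller change.

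Reads over event exons served as a proxy of gene level, with 1 event per gene. SNRPA1 had 359.4 RPM (reads scaled to the file total) in siSNRPB2 and 131.3 in siCtrl, 2.74-fold higher. Its log2 ratio was 1.45 (95% interval 1.38 to 1.52 for counting error, 1.24 to 1.67 with reads divided by the noise factor). It ranked 1 from the top among 3334 protein-coding genes with at least 1000 reads on average, a minimum chosen after the data were seen, where the SD of the log2 ratio was 0.263. CMPK1 (1.31), PSAT1, an enzyme of serine synthesis (1.24), MBNL2, a splicing regulator (1.09), and CBX1 (1.06) followed, and IRF3 (-1.12), IQSEC2 (-1.09) and SLFN5 (-1.07) were lowest. By the rule fixed in advance, with at least 100 reads, OSBP2 (-3.88) and MXD3 (-3.47) were lowest and CD209 (2.66) and TMEM246 (2.63) highest, all on few reads (13 and 231 for OSBP2). PLEC (0.00) and ERRFI1 (-0.02) were near 0, and so were BCL2L1 (0.07), NUMB (-0.06), MCL1 (-0.12) and CD44 (-0.19). CASP2 was at -0.86 and MDM4 at -0.23, on few reads.

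**Figure D3:**
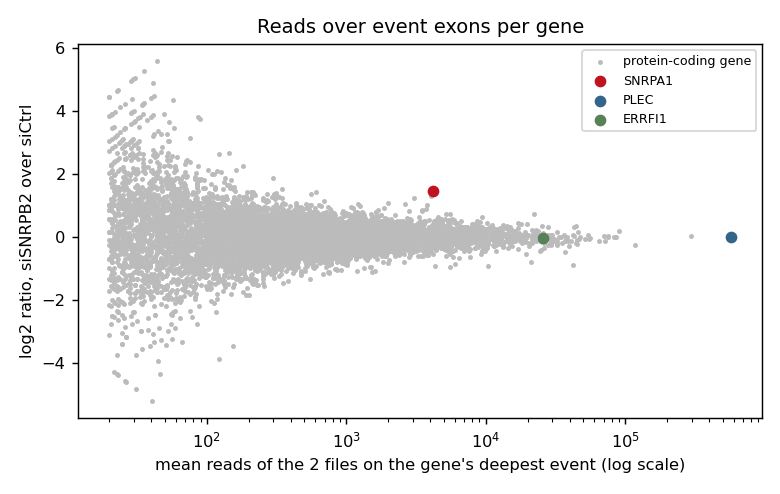
Log2 ratio of reads, siSNRPB2 over siCtrl (vertical axis), against mean reads on the gene's deepest event (horizontal axis, log scale); each point is a protein-coding gene. SNRPA1 lies at 1.45, above the other genes with at least 1000 reads, and PLEC and ERRFI1 lie near 0.

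As lists, 3 groups had median log2 ratios below the middle 95% of random lists matched on reads. Actin and adhesion genes had a median of -0.10 (percentile 0.16; 46 of 74 genes below 0), with TPM4, a tropomyosin, at -0.90. Membrane trafficking had a median of -0.09 (percentile 0.655; 56 of 93), with SNX14 at -1.13 but AP1G1 at 1.38 and COG7 at 1.28, and mitosis and cytokinesis a median of -0.09 (percentile 0.86; 51 of 84), although NDC80 (1.17) and CDC25A (1.03) were higher. Trafficking lost its place with reads summed over all events (percentile 11.1) or with at least 1000 reads (percentile 5.13). Mesenchymal markers, with 9 genes that went both ways (6 below 0 and 3 above, such as PDGFRB at 1.13 on few reads; median -0.25, mean 0.01), passed the threshold with at least 100 reads (percentile 2.14) or 1000 reads (percentile 1.52) but not with reads summed over all events (percentile 27.3). The remaining lists with at least 5 genes had percentiles of 2.68 (mesenchymal markers), 4.03 (DNA repair), 7.59 (genes with transition-associated exons), 33.7 (epithelial markers), 34.7 (SR proteins and hnRNPs), 51.6 (p53 pathway), 57.7 (nonsense-mediated decay), 57.9 (apoptosis), 59.0 (stress response), 65.0 (interferon genes), 71.4 (core spliceosome), 79.4 (U2 factors) and 95.1 (chromatin regulators). Of the blood and endothelial markers, 4 genes were measured, all on few reads, such as PTPRC with 8 and 51 reads.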

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

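In this part, the tests of the called exons were chosen only after the result was seen; those of the reads that fit neither isoform were set before. Reads that fit neither isoform of an event, such as intronic reads, were not used in the comparisons above. They made up 61.2% of event reads in siSNRPB2 and 59.1% in siCtrl, higher than in the control file. Over 7600 genes the median log2 ratio of such reads to compatible reads was 0.14 higher in siSNRPB2. A uniform background such as genomic DNA would raise the ratio most where these reads are sparse: the quintile of genes with the sparsest reads exceeded the densest quintile by 0.32 (95% bootstrap interval over genes 0.28 to 0.36), which is what such a background would give. More unspliced transcripts, which loss of a U2 protein could produce, were predicted to raise the densest quintile, where the median was 0.021 (0.00059 to 0.041). This lies between the bounds set for that explanation, so both explanations stay open.

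The 2754 calls, near-equal in both directions, were set against the noise of the reads. The median between-file chi-square in exons kept in nearly all transcripts was 9.35 times its expectation for independent reads, and 39.5% of calls had no exclusion-only read in either file. Such exons were a larger share of all tested exons (9550 of 18682). However, at least 3901 of them had a ψ of at least 0.95 in both files and could not be called. These shares therefore cannot show whether calls gathered in them. Given the noise factor, repeat reads or uneven coverage may account for many of the calls, but the scaled test had too little power to say which. For NASP noise of the median size in exons of its depth was argued against. Reads were divided by the upper end of the 95% bootstrap interval of the noise factor of each exon's own read quintile. The adjusted p of NASP was then 9.21e-14 by Fisher's exact test. That interval is for the median over exons, so larger noise in a single exon stays open. The factor was also measured against flanking reads, while the test uses exclusion-only reads. STAG2, SPTAN1, MMS19 and PTBP2 passed with the factor itself (adjusted p = 0.0321, 0.0431, 0.0182 and 0.00202 by the exact test) but not at that upper end (0.223, 0.269, 0.125 and 0.0728). PTBP2 lies in the quintile with the factor 5.99 (5.01 to 7.16) and MMS19 in that with 8.89 (7.82 to 10.7), while NASP, STAG2 and SPTAN1 lie in the deepest, with 11.8 (9.26 to 14.0). In the exons kept in nearly all transcripts, 0 of 780 in the deepest quintile differed as much as NASP, STAG2 or SPTAN1. For MMS19 it was 0 of 775. These counts cannot bound the noise, since the selection of those exons by ψ leaves out large shifts. NASP, STAG2, SPTAN1, MMS19 and PTBP2 were picked as the most extreme of 9132 with an exclusion-only read. For STAG2, SPTAN1, MMS19 and PTBP2 noise and a difference cannot be told apart. An effect of SNRPB2 loss on each of these exons was not tested, since there is 1 file per group.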

How the results depend on the processing

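The alternatives added after seeing the data were a minimum of 1 exclusion-only read, the noise factor of all exons or of the exon's own read quintile, other read minima for Fisher's exact test and at least 1000 reads per gene; the cause of a change was not tested unless given. No paired analysis was possible because the files hold 1 value per group, and no replicate could be left out for the same reason. Reads of SNRPB2 under other settings were not run, as no event was assigned to it. Lower and higher calls numbered 1422 and 1332. Without a read minimum they were 2554 and 2490, with Fisher's exact test in place of the Bayes factor 815 and 768, with the share of inclusion-only reads in place of ψ 759 and 754, and with at least 1 exclusion-only read 869 and 797. Requiring the noise-scaled test left 3 and 1. Lower and higher calls were 979 and 885 with at least 50 reads and 1000 and 877 at a mean ψ of 0.2 to 0.8, where fewer exons were tested. The share of lower calls stayed within its interval in all 15 alternatives run for it. The median ψ difference was -0.01 at a mean ψ of 0.2 to 0.8. Exons by Fisher's exact test fell from 1972 to 4 with the noise factor of all exons, to 5 with that of the exon's own read quintile and to 1218 with at least 50 reads. Of the exon features, 1 stood apart in the main setting, 2 with at least 50 reads and 5 when matched on reads alone. With the share of inclusion-only reads, which rests on few exclusion-only reads in these exons, SMG5 (0.0053), BCL2L13 (0.013), BID (0.023) and SMUG1 (-0.014) reversed. List percentiles under scaling by the median of gene ratios are nearly the same by construction.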

Other observations

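Both tests of SNRPA1 in this part were chosen after the result was seen. SNRPA1, which encodes the direct binding partner of the U2B'' protein, had the largest rise in reads among the 3334 protein-coding genes with at least 1000 reads. Uneven coverage of 1 event is argued against, since all 4 SNRPA1 events were higher in siSNRPB2, the lowest with a log2 ratio of 1.05. Events of 1 gene can share reads, so these are not 4 separate checks. Noise of the size measured within events is argued against too, since the lower bound with reads divided by the noise factor of all exons was 1.24. That factor does not cover differences between libraries in a gene's total reads, so such differences stay open. An effect of the siRNAs apart from SNRPB2 loss stays open, since the files hold 1 value per event and group, which cannot separate the siRNAs.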
